A study of Callosobruchus maculatus with 24 samples.

How the data were processed

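Gene expression was measured by RNA sequencing in abdomens and in combined heads and thoraces of virgin and mated Callosobruchus maculatus of both sexes. Per the labels' protocols, beetles were flash frozen, the abdomen was separated on ice, total RNA was extracted with RNeasy columns, and libraries were made with a stranded mRNA kit from Illumina. Each of the 24 libraries was sequenced on 2 lanes. The labels refer to the study's manuscript for the mating treatment, so the mating regime, the age of the beetles and the number of beetles per library are not given in the sources used here. Groups were taken from the source names in the labels, and no library was left without a group.

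The deposited tables hold estimated counts (expected counts) per gene and per transcript that are not normalised, 1 column per library with both lanes together; 14.1% of gene values are not whole. Per the submitters' processing notes, FastQC 0.11.2, cutadapt 1.2.1, Trimmomatic 0.3 and Bowtie 0.12.6 were used. The program that made the counts, the reference the reads were aligned to and whether strand was used in counting are not given in the sources used here. How reads shared between near-identical genes, or by overlapping and antisense genes, were split is thus unknown, and every single gene value carries that uncertainty. The 29812 genes and 58250 transcripts carry IDs that the files do not pair with names, so lists of named gene functions drawn up before the data were examined (from yolk and sperm genes to digestion and detoxification) could not be used. For 4524 genes the transcript counts summed to another value than the gene count by over 0.5 in at least 1 library.

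Estimated counts were rounded to whole numbers. Differences between groups were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group, and the robust quasi-likelihood test with 1 mean per group, and p-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05. The 12 libraries of a body part were fitted together, so that the 4 groups shared an estimate of the spread, and 14563 genes were tested in the abdomen and 13051 in the head and thorax. Comparisons between body parts used all 24 libraries and 15558 genes. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. Levels of single genes are CPM (counts relative to the scaled library total) with TMM factors over all 24 libraries. With 7805440 to 10171662 counts per library, a gene at 1 CPM before TMM scaling rests on about 8 to 10 counts per library, so that low genes are imprecise. The TMM factors, 0.867 to 1.21, widen this range in both directions.

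Sex-biased classes held genes at an adjusted p of 0.05 or less and at least 2-fold in the sex difference averaged over virgin and mated beetles, and body part classes genes at least 8-fold different in the same direction in both sexes. In this balanced design that average is independent of the mating effect, so the choice of a class gives the mating effect no direction. The classes were tested with fry of limma 3.58.1 on voom values, which asks whether the genes of a class move on balance in a direction and does not compare them with other genes, and with camera, adjusted over 16 tests of a class, sex and body part. Of these 16, fry called 5, camera with a preset correlation of 0.01 called 10, and camera with an estimated correlation called 1, the fall of female-biased genes in female abdomens. Sex-limited lists held genes with at least 5 CPM in the abdomens of a sex and at most 1/16 of that in the other; their summed CPM was compared with exact two-sided permutation tests, in which 3 against 3 libraries cannot give a p under 0.1. None of the 8 tests of these lists with fry passed the threshold (lowest adjusted p 0.6).

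Genes were named by a rule set before the data were examined: in each mating comparison the 2 rising and 2 falling IDs, and in each sex comparison the 1 and 1, with the largest log2 fold change among those past the threshold with at least 3 counts in every library of both groups and no overlap of the groups in CPM. Fewer were named where fewer passed. The design, the classes, the lists and most alternatives were also set before the data were examined: size factors of DESeq2 1.42.0 in edgeR, library size only, no or a stricter low-count filter (1 CPM in 3 libraries), DESeq2, limma-voom, a fit without robust estimation, a fit of all 24 libraries, fits of the 6 libraries compared, a replicate block, the transcript table, raised folds for classes (4 and 16) and lists (64), a raised list minimum (50 CPM), and each library left out in turn. Runs without the 10 most abundant genes and without 2 head and thorax libraries were added after the data were seen. The tests were tried on simulated counts drawn from the real means and library sizes with 200 changed genes. The changed genes were drawn from those with a mean of at least 1 CPM, so the rates found do not cover lower genes. Counts followed the negative binomial model that edgeR itself assumes, with spreads it estimated, so libraries that deviate otherwise are not covered. Smaller changes are not covered either, such as the median absolute log2 fold change of 0.45 among genes called in female abdomens. For the mating effect in female abdomens, over 14103 simulated genes, 57 of 100 genes changed 2-fold and 89 of 100 changed 4-fold were found, with 4 false calls among 150; in male heads and thoraces, over 12632 genes, these were 65 and 80 of 100 with 7 false calls among 152.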

Results

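RNA was sequenced from Callosobruchus maculatus, a seed beetle whose larvae feed inside stored legumes, in virgin and mated beetles of both sexes (strain South India). Abdomens and combined heads and thoraces were sequenced apart, which gave 8 groups of 3 libraries, 24 in all. Total counts per library ranged from 7805440 to 10171662. Group means ran from 7922142 ± 120511 (SD, n = 3) in virgin male heads and thoraces to 9862002 ± 441884 (SD, n = 3) in mated female abdomens. The gene table listed 29812 genes, of which 4364 had no count in any library. The files do not pair these IDs with gene names, so genes are described through their IDs and through classes set by sex and body part. Nothing in the labels says how many beetles made up a library or whether libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Libraries of a group all differed by more than sampling noise, with a lowest chi-square per degree of freedom of 5.82.

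In female abdomens, mating was accompanied by many small changes. Of 14563 genes tested, 1191 were higher and 915 lower in mated than in virgin females, and the median absolute log2 fold change of these 2106 genes was 0.45. Changes of at least 2-fold were seen in 113 of the higher and 64 of the lower genes. Genes with higher expression in female than in male abdomens fell: of 3349 female-biased genes, 503 fell, 116 rose and 2730 did not pass the test. Their median log2 fold change was -0.18 (fry, adjusted p = 2.93e-05; adjusted p = 0.00239 with an estimated correlation). Male-biased genes went the other way, with 514 of 3975 rising, 46 falling and 3415 not called. Their median was 0.18 (fry, adjusted p = 0.0276; adjusted p = 0.119 with an estimated correlation; 0.0566 to 0.0618 by fry without virgin female replicate 3 or any 1 mated female library). With the fold for sex bias raised to 4 the median of male-biased genes was 0.046 and the class did not pass (adjusted p = 0.705). Of 7239 genes with no 2-fold sex bias, 561 rose and 366 fell, and their median was 0.018. Among 120 genes enriched in the abdomen of both sexes, 22 rose and 1 fell (median 0.33; fry, adjusted p = 0.00363; adjusted p = 0.202 with an estimated correlation). Among 120 genes enriched in the head and thorax, 3 rose and 1 fell, and the class did not pass the test (median 0.30; fry, adjusted p = 0.3).

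Largest changes are given here and below among called genes with at least 3 counts in every library of both groups and no overlap of the groups in CPM, so that genes with lower counts may differ by more. The genes with the largest such increase in mated female abdomens, TR45430|c1_g5 and TR45058|c0_g1, were both lower in virgin female than in virgin male abdomens (log2 -6.45, SE 1.38, adjusted p = 0.00143, and log2 -5.19, SE 0.736, adjusted p = 7.13e-05). TR45430|c1_g5 stood at 12.05 ± 9.18 CPM (SD, n = 3) in mated against 0.322 ± 0.0388 CPM (SD, n = 3) in virgin females, a log2 fold change of 5.22 (SE 1.41, adjusted p = 0.0345). TR45058|c0_g1 stood at 33.2 ± 17.8 against 3.52 ± 1.85 CPM, a log2 fold change of 3.29 (SE 0.759, adjusted p = 0.0179). The largest such decreases were those of TR47510|c0_g1 and TR44554|c0_g1. The first went from 1.06 ± 0.334 to 0.296 ± 0.0443 CPM (log2 fold change -1.74, SE 0.362, adjusted p = 0.0103). The other went from 6.35 ± 1.35 to 1.87 ± 0.757 CPM (log2 fold change -1.70, SE 0.324, adjusted p = 0.00704). The call of TR45430|c1_g5 ended when any 1 of the 6 female abdomen libraries except mated replicate 3 was left out (adjusted p 0.0751 to 0.121). That of TR45058|c0_g1 ended without virgin replicate 2 or 3 or mated replicate 1 or 2 (0.0554 to 0.0707). Over all alternatives these calls ended in 9 and 6 of 17 (highest adjusted p 0.48 and 0.174). The call of TR47510|c0_g1 ended in 2 of 16, with limma-voom (0.0952) and in the fit of all 24 libraries (0.0648; range 0.00638 to 0.0952), and that of TR44554|c0_g1 in 0 of 17.

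The share of genes that rose in female abdomens depended on the scaling. With the size factors of DESeq2 in edgeR the split was 997 higher and 1178 lower genes, and with library size only it was 672 higher and 2270 lower. In the latter the median of all genes moved by -0.11. On that scale the female-biased median was -0.30 and the male-biased median 0.054, so that the classes stayed apart. The rise of the male-biased class no longer passed the test (adjusted p = 0.42 with the same genes; 0.031, adjusted p = 0.631 with the class rebuilt on that scale). Neither did that of the abdomen-enriched class (0.20, adjusted p = 0.107 with the same genes; 0.17, adjusted p = 0.228 rebuilt). The difference between the class medians, male-biased minus female-biased, was 0.36 with either scaling for the same classes, since a scale factor moves all genes of a library alike, and 0.31 with classes rebuilt on library size only. Leaving out any 1 of virgin replicate 2 and mated replicates 1, 2 and 3 lowered the number of genes called to between 1125 and 1327. Without virgin replicate 1 the split was 666 higher and 814 lower.

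**Figure D1:**
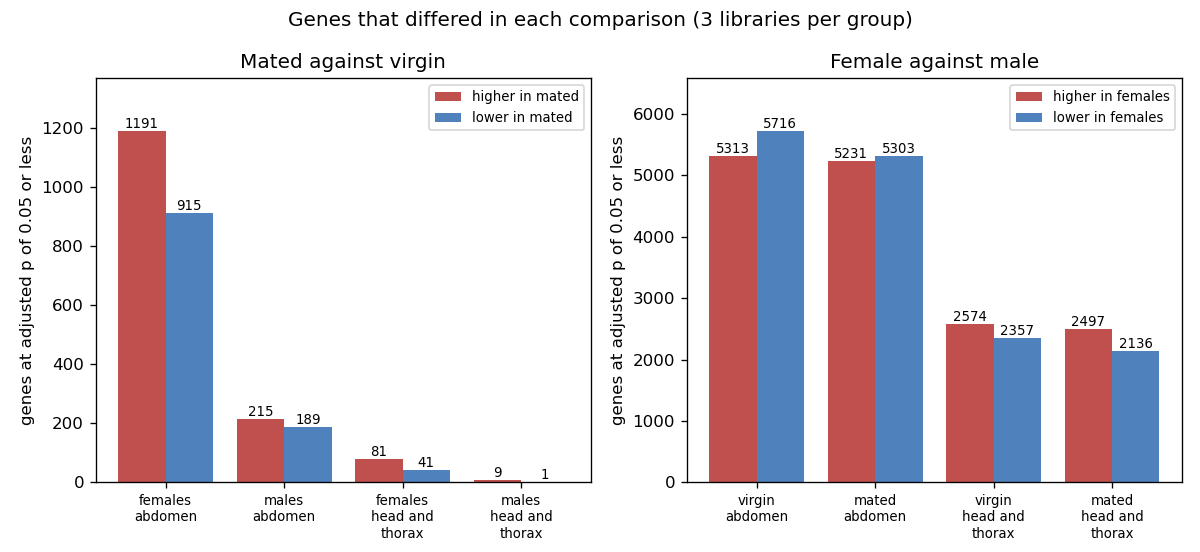
Numbers of genes higher (red) and lower (blue) at an adjusted p of 0.05 or less, between mated and virgin beetles (left) and between females and males (right), for each body part. Mating was accompanied by 1191 higher and 915 lower genes in female abdomens and by 9 higher and 1 lower gene in male heads and thoraces, with each vertical axis on its own scale and a split in female abdomens that turns with other scalings (997 higher and 1178 lower with the size factors of DESeq2).

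Male abdomens changed less in number of genes: 215 genes were higher and 189 lower in mated than in virgin males, with 39 higher and 10 lower genes at 2-fold or more. TR6918|c0_g1 rose from 1.01 ± 0.0755 to 18.3 ± 7.14 CPM (SD, n = 3 each; log2 fold change 4.12, SE 0.308, adjusted p = 0.00034), and kept its call in each of the 17 alternatives run. TR48097|c0_g1 rose from 24.3 ± 13.1 to 174 ± 41.6 CPM (log2 fold change 2.81, SE 0.396, adjusted p = 0.00785). Its call ended in 2 of 17 alternatives, the fit of all 24 libraries (adjusted p = 0.214) and that of the 6 libraries compared (0.0579), in a range from 4.11e-08 to 0.214. TR34856|c1_g5 fell from 3.03 ± 1.33 to 0.632 ± 0.460 CPM (log2 fold change -2.29, SE 0.412, adjusted p = 0.0169). TR27049|c0_g2 fell from 3.05 ± 1.29 to 0.671 ± 0.315 CPM (log2 fold change -2.21, SE 0.402, adjusted p = 0.0174). Of the 3975 male-biased genes 27 rose and 24 fell, with a median of -0.11 against -0.064 over all genes (fry, adjusted p = 0.0457; adjusted p = 0.544 with an estimated correlation). Of the 120 abdomen-enriched genes 1 rose and 3 fell (median -0.17; fry, adjusted p = 0.0363; adjusted p = 0.544 with an estimated correlation). Each of these 2 class calls ended in 9 of the 12 fits that left out 1 abdomen library of either sex (adjusted p 0.0534 to 0.369). Of the 3349 female-biased genes 18 rose and 40 fell, which did not pass the test (median -0.073; fry, adjusted p = 0.0851).

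With library size only, the split in male abdomens was 246 higher and 114 lower genes. Leaving out any 1 male abdomen library except mated replicate 2 lowered the number of calls to between 174 and 245. The call of TR34856|c1_g5 ended without mated replicate 1 or 2 (adjusted p 0.0543 to 0.0665), and that of TR27049|c0_g2 without virgin replicate 3 or mated replicate 1 or 2 (0.0534 to 0.0732). Over all alternatives these calls ended in 5 and 6 of 17 (highest adjusted p 0.162 and 0.155).

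Whether the sexes responded differently was tested with the sex-by-mating interaction, which called 1206 of 14563 genes in the abdomen. In 920 of these the sex difference was smaller in mated than in virgin beetles and in 286 it was larger, a share of 23.7% against 39.1% over all genes tested. With the main scaling the narrowing was seen on both sides. Among the called genes, 330 male-biased genes had a smaller and 36 a larger sex difference after mating. Of female-biased genes 159 had a smaller and 47 a larger one. With library size only, the 330 cannot be reached, since 302 genes in all were more positive in females. On that scale the median mating effect in females and males was 0.054 and -0.081 for male-biased genes and -0.30 and -0.040 for female-biased genes. Over all members of the classes, the median log2 sex difference moved from -2.26 in virgins to -1.90 in mated beetles for male-biased genes and from 1.89 to 1.75 for female-biased genes. The interaction was called for TR45430|c1_g5 (log2 6.94, SE 1.72, adjusted p = 0.0348) and TR45058|c0_g1 (log2 4.40, SE 0.944, adjusted p = 0.0195), both with a more positive mating effect in females. It was also called for TR6918|c0_g1 (log2 -4.12, SE 0.391, adjusted p = 0.00126), which rose in males. The mating effect was more positive in females than in males for 761 genes and more negative for 445, a split that turned to 302 and 885 with library size only and to 317 and 501 without virgin female replicate 1. Without mated female replicate 2 the interaction called 763 genes.

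Few genes were called in both sexes. In the abdomen, 40 genes were higher after mating in both sexes where 17.6 are expected from independent lists, 21 were lower in both (11.9 expected), and 43 moved in opposite directions (29.0 expected). Across the 14563 genes, the log2 fold changes of females and males had a Spearman correlation of 0.0026, which is across genes that are not independent replicates. Between the body parts of a sex the Spearman correlation was 0.193 in females (0.0747 without virgin head and thorax replicate 3) and 0.271 in males. The Pearson correlations were 0.0163 between the sexes in the abdomen and -0.0287 and 0.0816 between the body parts of females and males, and differences between correlations were not tested. In males, 8 of the 9 genes higher in the head and thorax were also higher in the abdomen (0.155 expected). In females, 31 genes were higher in both body parts (7.33 expected) and 24 lower in both (3.02 expected), and 3 moved in opposite directions (9.61 expected).

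**Figure D2:**
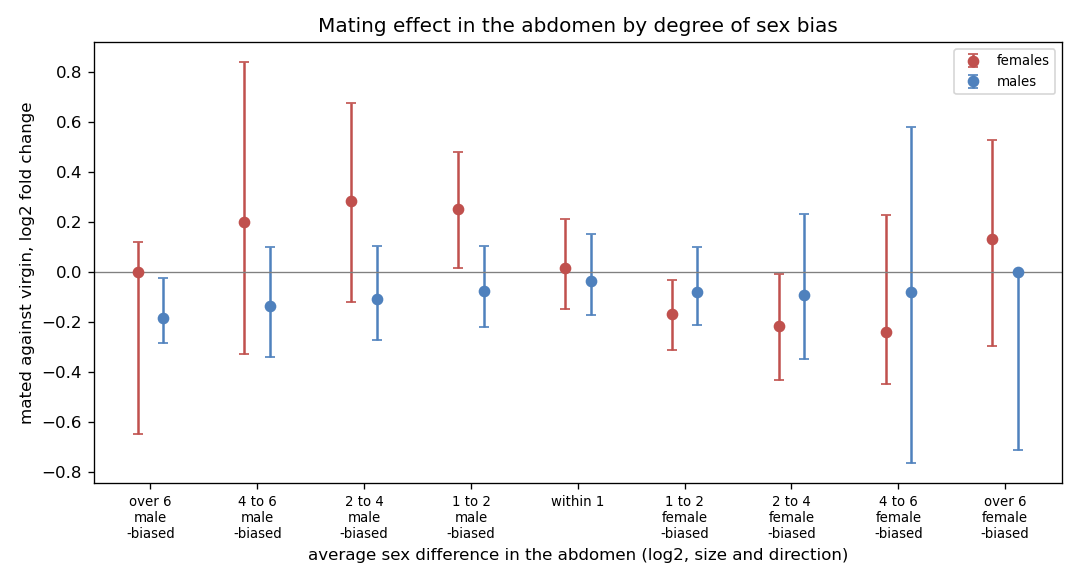
Median log2 fold change between mated and virgin beetles in the abdomen for genes binned by their average log2 sex difference, in females (red) and males (blue). Points are medians over genes and bars span the lower to the upper quartile; in females the medians run from 0.28 at a male bias of 2 to 4 to -0.24 at a female bias of 4 to 6 and are 0.13 above 6 and 0.00 at a male bias over 6, and with library size only all genes move down by a median of 0.11.

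Sex differences in the abdomen covered most of the transcriptome. Among virgins 5313 genes were higher in females and 5716 higher in males, 75.7% of genes tested, and among mated beetles 5231 and 5303 were. At 2-fold or more the numbers were 3353 and 4107 in virgins and 3083 and 3514 in mated beetles. The largest sex differences by that count rule were nearly complete. TR25775|c0_g2 stood at 8784 ± 614 CPM in virgin female and 3.57 ± 3.45 CPM in virgin male abdomens (SD, n = 3 each; log2 11.22, SE 0.457, adjusted p = 2.69e-09). TR69690|c0_g1 stood at 0.508 ± 0.362 and 2534 ± 163 CPM (log2 -12.35, SE 0.252, adjusted p = 8.97e-12). In mated beetles, TR61942|c0_g1 stood at 3774 ± 327 CPM in females and 0.789 ± 0.362 in males (log2 12.22, SE 0.287, adjusted p = 3.19e-11). TR64881|c2_g2 stood at 0.298 ± 0.0623 and 2840 ± 210 CPM (log2 -13.15, SE 0.271, adjusted p = 1.00e-11). Of the genes higher in females 4694 were called in both virgins and mated beetles (1908 expected), of those higher in males 4895 (2081 expected), and 74 changed sides (3988 expected). With library size only the virgin split was 6768 higher in females and 4335 higher in males.

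A list of 981 male-limited genes, with at least 5 CPM in male abdomens and at most 1/16 of that in female abdomens, made up 32.0% of normalised counts in male abdomens after mating and 31.3% before. Such percents are summed CPM with TMM factors, which were 1.13 to 1.21 in female and 0.899 to 0.951 in male abdomens. Shares of the counts themselves are thus higher in female and lower in male abdomens. In female abdomens the same list summed to 1046 ± 33.4 CPM in mated and 972 ± 95.5 CPM in virgin beetles (SD, n = 3 each). These sums did not differ in an exact permutation test (two-sided, p = 0.3, where the smallest p this design allows is 0.1). The limit of 1/16 covered mated as well as virgin female abdomens, so a male gene that rose enough after mating left the list. TR45058|c0_g1, at 3.52 CPM in virgin and 33.2 CPM in mated female abdomens, was left out in this way, as was TR45430|c1_g5. The sums can thus understate a rise of male genes. A list of 307 female-limited genes, by the mirror rule, rose in share in female abdomens from 15.8% to 22.1% of normalised counts (ratio 1.40), with no overlap between the 3 mated and 3 virgin libraries (exact permutation test, two-sided, p = 0.1, the smallest possible). The sum rests on its abundant members: of 305 tested, 55 rose, 39 fell and 211 were not called, with a median log2 fold change of -0.075 (fry, adjusted p = 0.631). In male abdomens this list summed to 1702 ± 115 CPM after mating and 1403 ± 175 CPM before (ratio 1.21, exact permutation p = 0.1), but without TR61957|c3_g2 to 702 ± 46.8 and 737 ± 32.7 CPM (ratio 0.953, exact permutation p = 0.4).

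Much of the female-limited share lay in TR61957|c3_g2, the most abundant gene of female libraries, which was also named by the rule in the sex comparisons of the head and thorax and was followed into other comparisons after its values were seen. It took 4.85 ± 0.725% of normalised counts in virgin and 8.93 ± 0.597% in mated female abdomens (SD, n = 3 each; log2 fold change 0.93, SE 0.166, adjusted p = 0.0052). In female heads and thoraces it took 8.39 ± 0.576% in virgin and 15.2 ± 0.792% in mated beetles (log2 fold change 0.85, SE 0.173), where the adjusted p of 0.0503 missed the threshold and ranged from 9.11e-05 to 0.179 over the alternatives. In females its level was lower in the abdomen than in the head and thorax (log2 -0.78, SE 0.122, adjusted p = 1.15e-05). In males it took at most 0.0999 ± 0.0109%, in mated abdomens. Its mating effect in males was 0.54 in the abdomen (SE 0.166, adjusted p = 0.116) and 0.56 in the head and thorax (SE 0.174, adjusted p = 0.366), and a difference between the sexes was not called (interaction log2 0.39, SE 0.233, adjusted p = 0.37, and 0.29, SE 0.244, adjusted p = 0.763). Without this gene the female-limited list rose by a ratio of 1.204 in female abdomens (exact permutation p = 0.1), and in female heads and thoraces the ratio of mated to virgin was 0.703 (4968 ± 160 against 7065 ± 4042 CPM, SD, n = 3 each; exact permutation p = 0.7). That fall rests on virgin replicate 3: with this library left out as well, the log2 ratio was 0.065 in place of -0.51.

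**Figure D3:**
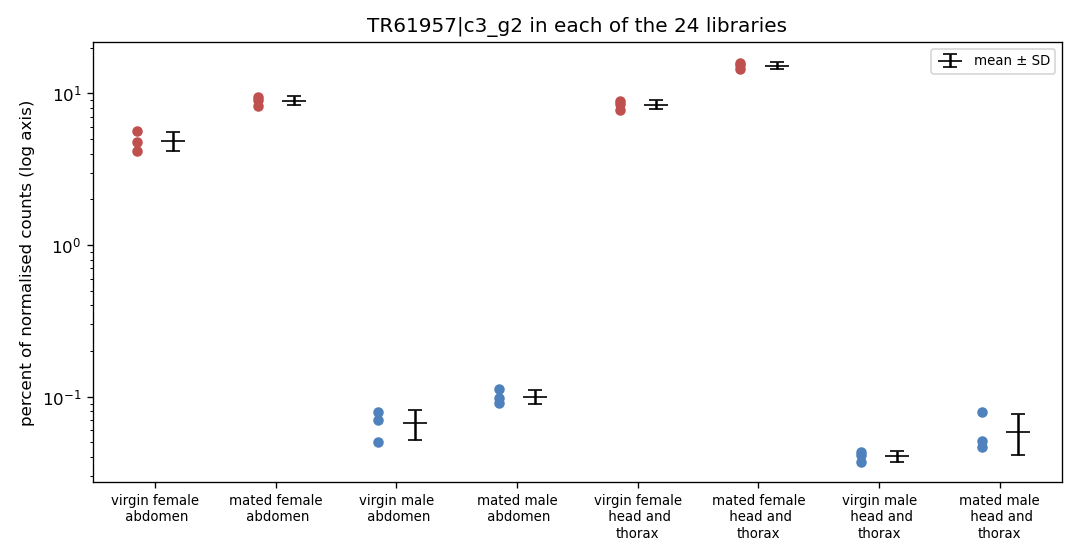
Percent of normalised counts taken by TR61957|c3_g2 in each of the 24 libraries, on a log axis, with points for libraries (red female, blue male) and bars for the mean ± SD of 3 libraries. Mated females lie above virgin females in both body parts (8.93% against 4.85% in the abdomen, 15.2% against 8.39% in the head and thorax), and male groups reach at most 0.0999%.

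In the head and thorax, mating was accompanied by few called changes. In females 81 genes were higher and 41 lower in mated beetles among 13051 tested. TR73931|c0_g1 was higher after mating (2.97 ± 1.23 against 0.757 ± 0.188 CPM; log2 fold change 1.95, SE 0.378, adjusted p = 0.0424), as was TR45364|c5_g8 (19.7 ± 8.49 against 6.04 ± 1.10 CPM; log2 1.69, SE 0.332, adjusted p = 0.0477). TR51689|c0_g2 was lower (55.0 ± 22.4 against 255 ± 70.1 CPM; log2 -2.23, SE 0.302, adjusted p = 0.0137), and so was TR4938|c0_g2 (8.59 ± 2.05 against 25.7 ± 4.15 CPM; log2 -1.59, SE 0.252, adjusted p = 0.0205). Of 1001 genes female-biased in this body part 8 rose and 3 fell, and of 573 male-biased genes 2 rose and 11 fell. Neither class passed the test (medians -0.13 and 0.017; fry, adjusted p = 0.659 and 0.688). In virgin replicate 3, 64 abundant female-limited genes that were nearly restricted to the abdomen stood at a median of 3.03% of their abdominal level, against 0.129% to 0.266% in the other 5 female libraries.

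Leaving out any 1 of the 6 female libraries lowered the number of calls to between 26 and 64, and each of these genes lost its call in at least 1 such case (highest adjusted p 0.157 for TR73931|c0_g1, 0.143 for TR45364|c5_g8, 0.0559 for TR51689|c0_g2 and 0.0821 for TR4938|c0_g2). The split was 57 higher and 124 lower genes with library size only, 249 and 254 with DESeq2, and 39 and 55 without virgin female replicate 3 and virgin male replicate 1.

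In male heads and thoraces 9 genes were higher and 1 lower after mating. TR57290|c1_g4 rose from 7.90 ± 1.94 to 19.9 ± 3.67 CPM (SD, n = 3 each; log2 1.35, SE 0.190). TR29718|c2_g8 rose from 20.1 ± 2.53 to 38.2 ± 4.46 CPM (log2 0.94, SE 0.130), and TR54179|c0_g2 fell from 10.1 ± 1.41 to 2.64 ± 0.311 CPM (log2 -1.92, SE 0.253). All 3 had an adjusted p of 0.0395. Of the 1001 female-biased genes 3 rose. The sex-by-mating interaction called 14 genes, among them TR54179|c0_g2 (log2 2.50, SE 0.347, adjusted p = 0.0256). When any 1 of the 6 male libraries was left out, each of these 3 named genes lost its call (highest adjusted p 0.14) and edgeR called between 0 and 4 genes. Without any 1 of 9 libraries (all but virgin female replicates 1 and 3 and mated female replicate 2) the interaction called between 0 and 7. With all libraries 1257 genes had an unadjusted p under 0.05 for the mating effect, DESeq2 called 189 genes for it and 268 for the interaction, and with library size only the interaction split was 7 and 51.

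Sex differences in the head and thorax reached 4931 genes in virgins, 2574 higher in females and 2357 higher in males, and 4633 in mated beetles, 2497 and 2136. By the count rule TR61957|c3_g2 had the largest female excess, a log2 difference of 7.82 in virgins (SE 0.231, adjusted p = 9.23e-09) and of 8.11 in mated beetles (SE 0.234, adjusted p = 7.08e-09). Among genes that pass the count rule, TR14545|c0_g1 had the largest log2 excess in mated males, at 201 ± 88.7 CPM against 4.63 ± 1.65 CPM in mated females (SD, n = 3 each; log2 -5.35, SE 0.541, adjusted p = 6.72e-05). TR45058|c0_g1 had it in virgins, by the same rule, at 589 ± 814 CPM in males against 1.58 ± 0.921 CPM in females (log2 -8.40, SE 2.22, adjusted p = 0.0146). In 1 male library, replicate 2, it stood at 1529 CPM. Of genes higher in females 1966 were called in both virgins and mated beetles (492 expected), and of genes higher in males 1571 (386 expected). Without that library the log2 difference was -6.07 (adjusted p = 0.0417). The call of TR45058|c0_g1 ended without virgin female replicate 1 or 3 (adjusted p 0.0503 and 0.0599).

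In virgin male replicate 1 of the head and thorax, male-limited genes of the abdomen were more abundant than in the other libraries. Over 372 such genes with at least 50 CPM in male abdomens and little in the head and thorax, the median level in this library was 6.36% of the abdominal level, against 0.0203% to 0.514% in the other 5 male libraries. The whole male-limited list summed to 10393 ± 4798 CPM in virgin and 7839 ± 578 CPM in mated male heads and thoraces (SD, n = 3 each; exact permutation p = 0.6). The levels in this library ranged widely: 316 genes had a median of 6.74% of the abdominal level, with quartiles of 5.85% and 8.42%. Of these, 33 lay more than 1.5-fold below that median, down to 0.648%. The remaining 56 genes stood under 0.1 times the median of all 372. Those 56 genes held 163378 of the 288136 CPM that the 372 genes summed to in male abdomens.

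**Figure D4:**
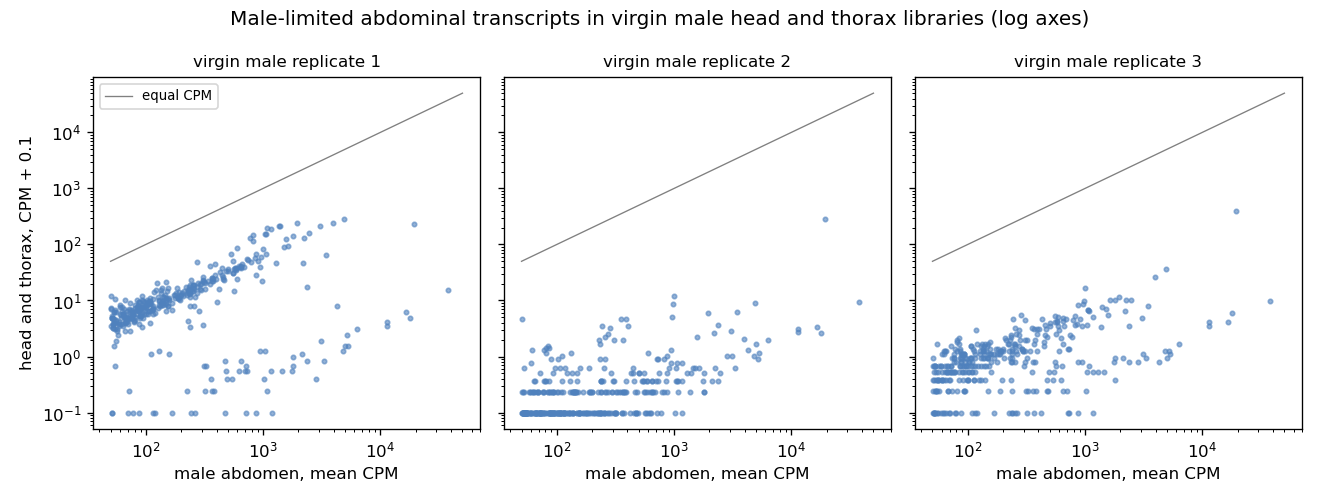
CPM of 372 male-limited abdominal genes in each virgin male head and thorax library (vertical, 0.1 added, log axis) against their mean CPM in male abdomens (horizontal, log axis), with 1 point per gene and a grey line at equal CPM. In replicate 1, 316 genes have a median of 6.74% of the abdominal level, with some as low as 0.648%, and 56 genes lie under 0.1 times the median of all; replicates 2 and 3 have medians of 0.0203% and 0.514%.

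Differences between body parts were called for 69.0% of genes in females and 60.8% in males, in a fit of all 24 libraries that took the body parts as independent samples. In females 6449 genes were higher in the abdomen and 4288 higher in the head and thorax among 15558 tested, and in males 4928 and 4532 were. At 2-fold or more the female numbers were 3126 and 2641 and the male numbers 2569 and 2001. The mating effect differed between body parts for 340 genes in females, more positive in the abdomen for 130 and more negative for 210, and for 3 genes in males. Most of these calls ended when the body parts were paired by replicate number. Of 24 splits of the mating labels, 5 gave as many calls in males, the real one included, so that chance was not excluded. In females 2 did, the real one and 1 that kept all 6 abdomens in their true groups, as set out below. In females, TR45364|c5_g8 went from 6.04 to 19.7 CPM in the head and thorax and stood near the floor in the abdomen, at 0.435 ± 0.528 CPM in virgin and 0.0293 ± 0.0508 CPM in mated females (SD, n = 3 each; 15 and 1 counts over 3 libraries). Its interaction (log2 -5.08, SE 1.22, adjusted p = 0.0399) thus rests on few counts, and its size depends on the fit. TR4938|c0_g2 went from 25.7 to 8.59 CPM and from 8.15 to 7.52 CPM (interaction log2 1.46, SE 0.306, adjusted p = 0.0195). The 3 genes in males fell outside the naming rule and were picked after their values were seen. TR10061|c1_g2 went from 345 ± 119 to 536 ± 60.7 CPM in the abdomen and from 269 ± 156 to 48.0 ± 7.47 CPM in the head and thorax (SD, n = 3 each, interaction log2 3.12, SE 0.476, adjusted p = 0.0194). Its virgin male groups thus varied widely, and that of the head and thorax includes replicate 1, which held abdominal transcripts. TR44314|c1_g4 went from 78.8 ± 5.84 to 215 ± 20.4 and from 156 ± 9.17 to 242 ± 13.6 CPM (log2 0.82, SE 0.125, adjusted p = 0.0194). TR8464|c3_g6 went from 812 ± 5.73 to 595 ± 28.7 and from 128 ± 14.9 to 154 ± 8.55 CPM (log2 -0.72, SE 0.0975, adjusted p = 0.0113). Leaving out any 1 mated female library, or virgin female abdomen replicate 2 or 3, lowered the female count to between 93 and 196, and leaving out single male libraries gave between 0 and 10 genes in males. DESeq2 called 873 genes in females and 62 in males, the transcript table gave 14 and 11 transcripts, and 1451 genes in males had an unadjusted p under 0.05.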

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

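The tests of carry-over, male RNA, tissue share and scaling (the distance between class medians and the medians of the same genes with library size only) were chosen after the patterns they bear on were seen; the interaction tests and the counts over other splits of the samples were planned.

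The mating effect differed between the sexes for 1206 genes in the abdomen and 14 in the head and thorax, and between body parts for 340 genes in females and 3 in males, by the interaction test of edgeR. Among named genes of the abdomen, the interaction (female minus male mating effect, log2) was 6.94 for TR45430|c1_g5, 4.40 for TR45058|c0_g1, -1.75 for TR47510|c0_g1, -4.12 for TR6918|c0_g1, 2.17 for TR34856|c1_g5 and 1.91 for TR27049|c0_g2. In the head and thorax it was 2.50 for TR54179|c0_g2. The interaction of body part and mating in females (abdomen minus head and thorax) was -5.08 for TR45364|c5_g8, of which the abdomen held 15 counts in virgin and 1 in mated females, so that its size is not determined, and 1.46 for TR4938|c0_g2. Of 24 splits that shuffled mating status within each sex, 1, the real one, gave as many interaction calls, in the abdomen (1206 against at most 198) and in the head and thorax (14 against at most 12). That is the smallest share that 24 splits can give, so it speaks against chance for the mating labels as a whole without excluding it. Since the shuffles also break the mating effect of each sex, they do not test the interaction alone. In the head and thorax the margin was small: both splits with 12 calls kept or mirrored the mating status of all 6 female libraries, and leaving out single libraries gave 0 to 15 calls by edgeR (14 with all libraries, where 1226 genes had an unadjusted p under 0.05 and DESeq2 called 268). For the interaction of body part and mating, 2 of 24 splits gave as many calls in females and 5 of 24 in males, so that chance was not excluded; the other splits reached 633 calls against 340 and 20 against 3. The split with 633 calls kept all 6 female abdomens in their true groups and exchanged 1 pair of head and thorax libraries, so that it still carried the mating effect of the abdomen. Body part itself gave 10737 calls in females against at most 6, and 9460 in males against at most 6717 (1 of 24 splits each); the splits of males with 5681 to 6717 calls kept or mirrored the body part of all 6 libraries of a mating status and exchanged 1 pair in the other. For the mating effects, 3 against 3 libraries make 10 splits, too few for a share under 0.05: the real and the highest other count were 2106 and 1 in female abdomens, 404 and 3 in male abdomens, 122 and 1 in female heads and thoraces, and 10 and 3 in male ones. For the sex differences they were 11029 and 0 and 10534 and 0 in virgin and mated abdomens, and 4931 and 0 and 4633 and 1 in virgin and mated heads and thoraces.

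The transcript table, which served only for alternative runs, lacked 6.80% of the gene table's counts in mated and 6.55% in virgin male abdomens, against 1.06% to 1.46% in the other groups. TR71873|c3_g2, the most abundant gene of male abdomens at 38192 ± 3230 CPM after mating, accounted for 33.9% of all missing counts and TR42691|c2_g3 for 14.9%.

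The fall of female-biased and rise of male-biased genes in mated female abdomens was set against 3 explanations. A scale factor moves the log2 fold changes of the edgeR fit alike for all genes, so it cannot give the distance of 0.36 between the class medians there. In the 9 pairs of a mated and a virgin library (log2 of CPM + 1, library size only) the distance was 0.261 to 0.363. On that measure genes near 0 CPM move less, so a scale factor can give some distance, though none larger than its own shift. Scaling alone is thus argued against for the distance between the class medians. It is not argued against for the rise of male-biased genes: their median was 0.18 with the main scaling (quartiles -0.049 and 0.51) and 0.054 for the same genes with library size only (quartiles -0.17 and 0.39; adjusted p = 0.42), where the median of all genes moved by -0.11 and the call ended. Over the 9 pairs (log2 of CPM + 1) their median was 0.0070 to 0.097 with the main scaling and 0 to 0.061, above 0 in 4 pairs, with library size only. That of female-biased genes was -0.28 to -0.18 and -0.31 to -0.26, so that on this measure most of the distance came from the fall of female-biased genes. Genes near 0 CPM in females, as most of the 1000 genes with a log2 male bias over 6, can change little on this measure. It can thus understate a rise of male-biased genes. By the edgeR fit with the main scaling the female-biased and male-biased medians were -0.18 and 0.18. Male RNA carried into females at mating is argued against as well, for RNA in the proportions of the whole male abdomen. With the main scaling, the rise of 2099 male-biased genes would need 4.14% of male abdominal RNA. These genes were not male-limited and had a mean of at least 1 CPM in virgin female abdomens. That share would raise the male-limited list by 13113 CPM, where 73.6 CPM (SE 58.4) was seen. The rise seen can be too low, because male genes that rose enough in mated females, such as TR45058|c0_g1 and TR45430|c1_g5, left the list. RNA of a part of the male abdomen that holds less of this list stays open. A lower share of all female-specific abdominal tissue, with unchanged expression within it, is argued against by 122 female-limited genes restricted to the abdomen. Their median was above 0 in each of the 9 pairs (0.291 to 0.485). The other 183 female-limited genes, also expressed in the head and thorax, fell (median -0.24, with 9 risen, 35 fallen and 139 not called). A lower share offset by higher expression of the 122 genes is not excluded. A lower share of a single tissue, or a change of expression within tissues, may underlie the pattern and was not tested.

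In virgin male head and thorax replicate 1, male-limited genes of the abdomen were set against carry-over at dissection. RNA of the whole abdomen is argued against, because 56 of the 372 genes, which held 56.7% of the list's summed CPM in male abdomens, stood under 0.1 times the median ratio. Carry-over of a part of the abdomen is a candidate explanation, since 63.2% of all 372 genes lay within 1.5-fold of their median ratio of 6.36%. Levels between this ratio and that of the 56 genes were seen as well, down to 0.648%. Which part could not be named, because the IDs carry no gene names, and no biological explanation was tested.

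TR61957|c3_g2 in female heads and thoraces was set against carry-over from the abdomen, and that is argued against: its level in the head and thorax exceeded that in the abdomen in each of the 18 pairs of female libraries of a mating status (ratio 1.39 to 2.14), which RNA in the proportions of the abdomen cannot give. Carry-over of a part of the abdomen richer in this gene stays open. Expression outside the abdomen may account for it, as a hypothesis; a tissue was not tested.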

How the results depend on the processing

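Runs without the 10 most abundant genes or without 2 head and thorax libraries, runs without the most abundant gene of a list or with library size only for the same class members, the results on female-limited genes in females and on the difference of class medians, and the choice of TR61957|c3_g2 came after the data were seen; the other alternatives were planned. Of the alternative values, 588 of the results that answer a comparison kept their side of the threshold or stayed within their limits, 110 moved, 29 lost a call and 4 gained one. Counts of calls were judged by their total alone, within 1.5 times. A split that turned could thus count as kept, as in female abdomens and for the abdominal interaction with library size only. A turned sign of a difference between class medians counted as moved. No class median and no named gene turned its sign past the threshold. Of the named genes' values 362 were unchanged in call, 94 lost and 7 gained it. In heads and thoraces the calls for mating ended in 10 of 18 alternatives for TR73931|c0_g1, TR45364|c5_g8, TR57290|c1_g4 and TR54179|c0_g2, in 11 for TR29718|c2_g8, in 6 for TR4938|c0_g2 and in 3 for TR51689|c0_g2, and the virgin sex difference of TR45058|c0_g1 in 4. The sex differences and the body part differences stayed within 1.5 times in every run except sex differences of the head and thorax in the transcript table. Except where a smaller number of libraries or of counts per feature lowers the power, the cause was not tested. Depth limits low genes most, since 1 CPM before TMM scaling is about 8 to 10 counts.

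DESeq2 called more: 3259 and 1031 genes for mating in female and male abdomens, 503 and 189 in female and male heads and thoraces, 268 for the interaction with sex in the head and thorax, and 873 and 62 for that of body part and mating in females and males. The transcript table, which spreads counts over more features, called fewer: 341 and 68 for mating in abdomens, 9 and 0 in heads and thoraces, 210 and 0 for the interaction with sex, 14 for that with body part in females, and 3159 and 2872 for sex in virgin and mated heads and thoraces (for the counts of 0, edgeR on genes called 10 and 14, and DESeq2 189 and 268). For the interaction with body part in males it called more, 11 transcripts against 3 genes. Without a filter, 262 genes were called in male abdomens and 207 for the body part interaction in females. Fits of only the 6 libraries compared called 104 in male abdomens, 40 in female and 0 in male heads and thoraces. The fit of all 24 libraries called 281 and 44 in female and male heads and thoraces and 104 for their interaction. With library size only, 22 genes were called in male heads and thoraces and 58 for the interaction; limma-voom called 5 in male heads and thoraces. Without virgin female replicate 3 and virgin male replicate 1 of the head and thorax, 6 genes were called in males, 1 for the interaction with sex, 515 and 5 for that with body part in females and males, and the difference of class medians in female heads and thoraces was -0.043.

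With library size only, and classes rebuilt on that scale, class medians lost their call for male-biased genes in females (0.031, adjusted p = 0.631) and males (-0.10, 0.352) and for abdomen-enriched genes in females (0.17, 0.228) and males (-0.14, 0.228). With the same genes in the classes these calls ended as well (0.054 and -0.081, both 0.42, and 0.20, 0.107, and -0.14, 0.166, in that order). With raised class folds they lost it for male-biased genes in females (0.046, 0.705) and males (-0.15, 0.259) and for abdomen-enriched genes in males (-0.19, 0.0693), and the difference of class medians in female heads and thoraces rose to 0.42 from 0.15. The female-limited sum (log2 ratio of mated to virgin) in female abdomens was 0.48, and 0.54 with a list ratio of 1/64, 0.40 with raw library sizes and 0.27 without its most abundant gene. In female heads and thoraces it was 0.79, and 0.70 with raw library sizes and 0.75 to 0.82 with 1 library left out. Without that gene it was -0.51, which rests on virgin replicate 3, and 0.065 without both the gene and this library. In male abdomens it was 0.28, and 0.47 with the ratio of 1/64 and -0.070 without the gene.

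Leaving out 1 library at a time gave 1125 to 1480 calls for mating in female abdomens, 174 to 298 in male abdomens, 26 to 64 in female and 0 to 4 in male heads and thoraces. It gave 763 to 1080 for the interaction with sex in the abdomen and 0 to 15 in the head and thorax, and 93 to 440 and 0 to 10 for the interaction with body part in females and males. Class medians ranged from 0.14 to 0.20 for male-biased and from 0.18 to 0.32 for head-and-thorax-enriched genes in female abdomens (the latter passing without mated male replicate 1, adjusted p = 0.0174), and in male abdomens from -0.11 to -0.016 for female-biased (passing without virgin female replicate 2 or mated male replicate 2, 0.0215 and 0.0336), -0.14 to -0.055 for male-biased and -0.20 to -0.095 for abdomen-enriched genes. The difference of class medians in female heads and thoraces ranged from -0.0050 to 0.33, lowest without virgin female replicate 3. The share of head and thorax interaction genes with a larger sex difference after mating ranged from 0% to 100%. The correlation of female mating effects between body parts ranged from 0.0747, without virgin female head and thorax replicate 3, to 0.253, and the female-limited sum from 0.46 to 0.57.

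Replicate numbers recur across groups, and libraries of a number did not deviate together: of 84 pairs 6 had a correlation over 0.1 (range -0.178 to 0.192; -0.126 to 0.0787 for the 12 pairs of body parts of a sex and mating status), so the numbers were not taken as pairs. With the replicate block, 36 and 2 genes were called for mating in female and male heads and thoraces and 1 for their interaction (100% with a larger sex difference after mating). For mating in female and male abdomens it gave 1890 and 296 calls, and female-biased genes in male abdomens passed the test (-0.073; fry, adjusted p = 0.0172). In the fit of all 24 libraries the block was sex, mating status and replicate number, which pairs the body parts. The interaction with body part then called 29 and 1 genes in females and males, against 340 and 3 without the block. The tests of named gene lists were not run, because the IDs carry no names.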

Other observations

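The tests on female-limited genes, sex-limited genes and variable genes given here were chosen after the values were seen.

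Female-limited genes of the abdomen split by where else they were expressed. The 122 genes at least 8-fold higher in the abdomen than in the head and thorax of females rose after mating in female abdomens: 46 rose, 4 fell and 72 did not pass the test, with a median log2 fold change of 0.44 (fry p = 1.03e-06; camera p = 0.00131 with an estimated correlation). Their sum went from 87019 ± 5134 to 113398 ± 7626 CPM (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). The other 183 genes fell: 9 rose, 35 fell and 139 did not pass, with a median of -0.24 (fry p = 2.14e-05; camera p = 0.00925 with an estimated correlation). Without TR61957|c3_g2, which is among them and rose, their sum went from 22304 ± 727 to 18225 ± 401 CPM. With library size only the medians were 0.31 and -0.36, against -0.11 over all genes.

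The degree of sex bias went with the mating effect in female abdomens along a curve. Medians were 0.25 for 2045 genes with a log2 male bias of 1 to 2, 0.28 for 845 genes at 2 to 4, 0.20 for 302 genes at 4 to 6 and 0.00 for 1000 genes above 6, most of which are near 0 in females. On the female side they were -0.17 for 2038 genes at 1 to 2, -0.21 for 1095 genes at 2 to 4, -0.24 for 258 genes at 4 to 6 and 0.13 for 257 genes above 6, of which 46 rose and 14 fell. In males the medians lay between -0.18 and 0.00 in all 9 bins.

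By the ratio of 1/16 and the minimum of 5 CPM in each part, 52 genes in males and 84 in females counted as sex-limited in both body parts. These counts depend on the head and thorax libraries that held abdominal transcripts: without virgin male replicate 1 and virgin female replicate 3 they were 22 in males, all among the 52, and 66 in females, 63 of them among the 84. Of the 22 male genes 10 were higher in the head and thorax than in the abdomen, and of the 66 female genes 4 were.

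TR45430|c1_g5 and TR45058|c0_g1 varied widely between libraries of a group. In virgin male heads and thoraces they stood at 35.4, 586 and 39.1 CPM and at 96.8, 1529 and 141 CPM, each highest in replicate 2. In mated female heads and thoraces TR45058|c0_g1 stood at 1.21, 1.82 and 170 CPM, and TR45430|c1_g5 at 0.242, 0.568 and 0 CPM.

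In virgin female head and thorax replicate 3, 47 of the 64 abundant female-limited genes stood at 5.96% of their abdominal level or less, with a median of 2.69%, and 17 stood at 10.2% or more, with a median of 16.5%. The limit between them was set after the values were seen.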
